A study of Mesocricetus auratus with 8 samples.

How the data were processed

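Hearts of 8 female golden hamsters (Mesocricetus auratus) were sequenced as polyA RNA, 1 library per animal. Per the labels, RNA was extracted with Trizol and captured with polyA probes before fragmentation and adaptor ligation. The deposited values are counts, whole numbers per gene and library. They were taken as not normalized, and the library totals differ, though differing totals alone do not settle this. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM were used, with no version for RSEM and no role for any of the tools. The genome build, the annotation and whether RSEM estimates were rounded to whole numbers are not given in the sources used here. Reads shared between near-identical genes may therefore have been split or counted in either copy. Zbtb16 appears both under its symbol and under an identifier that the gene table pairs with the same symbol, so its counts are uncertain.

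Genes are named as the count table names them. Of 4676 identifiers that begin with LOC, 543 took the symbol that the RefSeq gene table of assembly BCM_Maur_2.0 pairs with the same gene number, and the rest keep their identifier. That table was used only for names and for which genes neighbour each other. The table holds 11 rows with date-like names, the kind a spreadsheet makes of gene symbols, and 15 rows whose name repeats another with a suffix, and these were kept as they stand. All 8 columns of the table matched a library label and none was left unused.

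Counts were scaled between libraries with the trimmed mean of M-values (TMM, edgeR 4.0.16 in R 4.3.3), with factors from 0.960 to 1.05, and given as CPM of the scaled total. Log2 values used a prior count of 0.5. Genes with a mean count of at least 50 over the 8 libraries, 10909 in all, were examined for spread. The range of a gene is the log2 CPM of its highest library minus that of its lowest, and the trimmed range is that of its second-highest minus its second-lowest. A gene was counted when the range was at least 1, that is 2-fold, and a chi-square test of its counts against equal relative abundance had a Benjamini-Hochberg adjusted p under 0.05. This test and the exact 95% Poisson intervals measure counting error only, and counts of reads without molecular identifiers are not independent molecules. The floor of a library was set at 3 counts of its total.

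Gene lists, 36 in all, for cell programs, cell types, neighbouring tissues and housekeeping were fixed before the data were examined. For each list with at least 3 measured members, the median range of the members was placed among the medians of 10000 random lists of the same size, matched on mean abundance in 20 bins, and the 95th percentile served as the threshold. This describes these libraries and is not a test of a group. Lists with fewer than 3 members past the filter (T and NK cells, B and plasma cells, neutrophils and mast cells, erythroid cells, skeletal muscle, lung epithelium, thymus, cartilage and bone, and liver) were given no percentile. Relations across libraries used Pearson's r and Spearman's rho with exact two-sided permutation p-values over all pairings of the 8 libraries, adjusted by Benjamini-Hochberg within each coefficient over the 7 relations tested. No r was given where either measure had a gap of over 0.5 of its range with at least 2 libraries on both sides.

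The rule for the genes named was fixed in advance. It took Myh6 and Myh7, up to 4 members of each list with the highest median CPM and up to 4 with the largest trimmed range, the 25 genes with the largest trimmed range, the 10 with the largest full range and the 10 with the highest median CPM. Nppb and Per2 are named because a relation fixed in advance contains them. Results planned for Myh6, its range and its share of Myh6 plus Myh7 counts, were not computed, because no row is paired with either symbol.

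The method was tested on simulated data. Poisson counts were drawn for the 10909 genes from their mean abundance and the library sizes, with 200 genes changed in 4 libraries each. Of 100 genes changed 2-fold, 97% were past the full range and 74% past the trimmed range; of 100 changed 4-fold, 100% were past both. None of the 10709 unchanged genes was counted by either range (0 in each case), and 8 passed the chi-square threshold. Of 100 random lists of a random value, 5% lay past the percentile threshold. This checks the calculation only, since the members of a real list can vary together.

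The counts of variable genes, the list percentiles by the trimmed range, the relations and the ranges of the named genes were recomputed with DESeq2 1.42.0 size factors, with plain total counts, and without each library in turn. The list percentiles by the full range, the leading axis, the chi-square count and the pairwise correlations were not. The counts of variable genes were also taken with no count filter, with a mean count of at least 500, with a prior count of 5 and with the 10 most abundant genes left out of the scaling. That last setting was planned to leave out mitochondrially encoded genes too, but none was found among the rows. For the relations, the median and the mean z-score replaced the mean of a list's members. After the data were seen, a setting without genes shared by both lists of a relation and a setting without liver genes were added. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.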

Results

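The dataset comprised polyA RNA sequencing of the hearts of 8 female golden hamsters killed at 25 weeks of age. According to the series design, the animals were either wild type or carried a loss of heterozygosity at Myh6, the gene of the alpha cardiac myosin heavy chain, and were sampled before dilated cardiomyopathy began. The labels named each animal by a code (M5F5, M5F7, M5F12, M5F16, M5F19, M5F22, M5F55 and M5F56) and gave none of them a genotype. No comparison of genotypes was therefore made, and no library was treated as a replicate of another. Values are given per library, or as the range and the median over the 8 libraries.

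Total counts lay close together, from 13608500 in M5F56 to 15255764 in M5F19, a ratio of 1.12. Of 20360 genes in the table, 16958 had at least 1 count in some library, and each library had a count for 15244 to 15542 of them. A count of 3, the limit that a count of 0 allows, corresponded to 0.197 to 0.220 CPM (counts scaled to library size). Rank correlations between libraries, taken across genes that are not independent of each other, ran from 0.968 to 0.990 over the 28 pairs. The chi-square per gene was 11.2 to 46.0 over the same pairs, where counting error alone gives about 1, so no pair of libraries was a duplicate within sampling noise.

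The most abundant transcripts with a known name were those of the ventricular contractile apparatus and its oxygen and calcium supply. Mb, the oxygen store myoglobin, had a median of 22966 CPM (20429 to 24787). Tpm1, the thin filament tropomyosin, had a median of 14040 CPM (12216 to 15176), and Tnnt2, cardiac troponin T, 9883 CPM (8683 to 11330). Atp2a2, the calcium pump of the sarcoplasmic reticulum, had a median of 12791 CPM, with its highest value of 15664 in M5F12 and its lowest of 10284 in M5F5. Its inhibitor Pln had a median of 6511 CPM (5994 to 6977). Myl2 and Myl3, the ventricular myosin light chains, had medians of 12840 CPM (10804 to 16118) and 7391 CPM (5944 to 8818), and Actc1, cardiac alpha actin, 9221 CPM (7486 to 10769). These 8 genes and 2 unnamed identifiers made up the 10 most abundant, which together took 10.9 to 12.9% of the counts of a library. Between the highest and the lowest library Pln, Mb, Tpm1, Tnnt2 and Actc1 spanned 1.16-fold to 1.44-fold, and the other 5 spanned 1.48-fold or more.

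Myh6 itself could not be reported by name. The count table holds no row under the symbol Myh6 or Myh7, and the gene table used for names (assembly BCM_Maur_2.0) paired neither symbol with a row of the counts. The planned range of Myh6 and its share of Myh6 plus Myh7 counts were therefore not computed. The pair of unnamed identifiers among the 10 most abundant, LOC101825281 and LOC106022467, neighbour each other between Ngdn and Cmtm5 in that gene table, and which genes they are was not settled here. LOC101825281 ranged from 11628 CPM in M5F12 to 21109 CPM in M5F22, with a median of 17814. LOC106022467 ranged from 5567 CPM in M5F56 to 10919 CPM in M5F5, with a median of 6633.

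Nppa, Angptl4, Klhl31 and Atf3 were among the 25 genes with the widest trimmed range, the range left after the highest and the lowest library of a gene are dropped. Nppa, which encodes atrial natriuretic peptide, was at 971 CPM in M5F5 (95% Poisson interval 955 to 988), 382 in M5F55, 305 in M5F19, 215 in M5F16, 139 in M5F22, 103 in M5F56, 53.5 in M5F7 and 53.2 in M5F12 (49.5 to 57.1). Angptl4, a secreted inhibitor of lipoprotein lipase, ran from 1.47 CPM in M5F56 and 3.89 in M5F19 up to 39.5 in M5F12. Klhl31, a Kelch-family gene of striated muscle, was at 53.9 CPM in M5F5 and 55.1 in M5F7 but at 399 in M5F19. Atf3, a stress-induced transcription factor, was at 273 CPM in M5F19 and 8.69 in M5F56, with 19.8 to 79.8 in the other 6.

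Of 10909 genes with a mean count of at least 50, 9423 (86.4%) differed among the libraries beyond counting error (chi-square test, Benjamini-Hochberg adjusted). The highest library exceeded the lowest at least 2-fold for 1519 of these genes. After the highest and the lowest library of each gene were dropped, 311 genes still spanned 2-fold or more. The median gene spanned 1.45-fold, or 1.25-fold between the second-highest and the second-lowest library. Leaving out 1 library gave 143 to 276 genes in place of 311, and with 1 library fewer a trimmed range is narrower by construction. The lowest counts were 169 without M5F5 and 143 without M5F7. These intervals and tests cover counting error only, and the spread between animals includes whatever genotype each one had. The libraries were not extreme equally often. Among genes spanning 2-fold, taken without the chi-square threshold, 313 were highest in M5F7, 313 in M5F19 and 79 in M5F55. The lowest value lay in M5F7 for 309 of them and in M5F55 for 70. Counts of list members highest or lowest in a library, given below, were not adjusted for this.

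**Figure D1:**
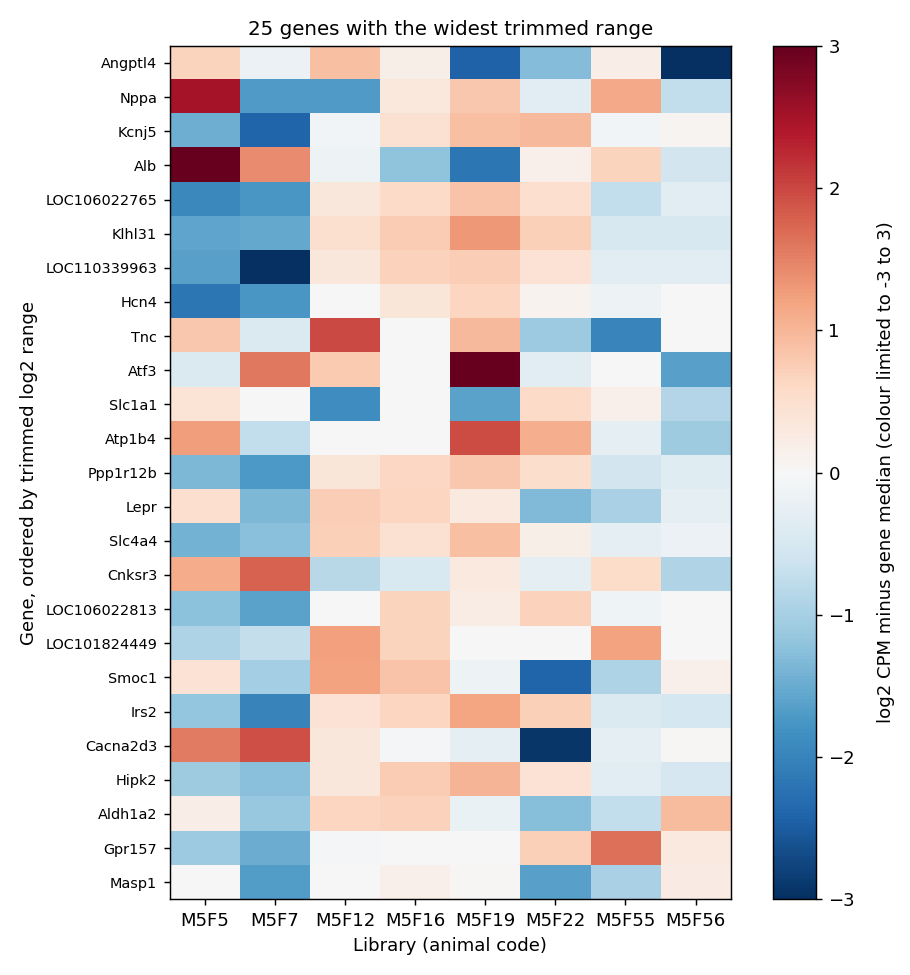
Heat map of the 25 genes with the widest trimmed range (rows, widest at the top) in the 8 libraries (columns, by animal code), coloured by log2 CPM minus the gene's median, with the colour limited to the range shown on the scale. Nppa stood at 971 CPM in M5F5 and Klhl31 at 399 CPM in M5F19, the far red cells of their rows, while Angptl4 stood at 1.47 CPM in M5F56.

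Also among these 25 genes, Hcn4, a pacemaker channel, ran from 3.78 CPM in M5F5 to 26.7 in M5F19, with a median of 17.1. Kcnj5, a subunit of the acetylcholine-activated potassium channel, ran from 3.15 CPM in M5F7 to 32.9 in M5F22 (median 16.7). Ppp1r12b, a regulatory subunit of myosin phosphatase, ran from 21.7 CPM in M5F7 to 124 in M5F19 (median 73.2), and the kinase gene Hipk2 from 26.2 to 126 CPM in the same libraries (median 64.1). Irs2, an adaptor of the insulin receptor, was lowest in M5F7 at 2.40 CPM and highest in M5F19 (95% Poisson interval 19.6 to 24.5), with a median of 10.1. Cnksr3, a scaffold of sodium channel regulation, was highest in M5F7 at 141 CPM and lowest in M5F56 at 22.4 (median 42.4). Smoc1, a matricellular gene, ran from 1.84 CPM in M5F22 to 22.5 in M5F12, and Lepr, the leptin receptor, from 2.47 CPM in M5F7 to 10.6 in M5F12.

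The fetal and stress response list, genes re-expressed in a strained heart, varied more than abundance-matched random lists. Its 15 measured members had a median fold of 2.38 between the highest and the lowest library, at the 100th percentile of 10000 random lists of the same size. Besides Nppa, Nppb, the gene of brain natriuretic peptide, ran from 260 CPM in M5F56 to 1361 in M5F19. Ankrd1, a cardiac ankyrin repeat gene induced by stretch, was at 1255 CPM in M5F56 and 3945 in M5F19. Acta1, skeletal alpha actin, ran from 3381 CPM in M5F16 to 7642 in M5F19. M5F19 held the highest value of 9 of the 15 members and M5F56 the lowest of 5. Fhl2 and Xirp2, which encode proteins of the sarcomere and its junctions, spanned 1.82-fold and 1.55-fold.

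**Figure D2:**
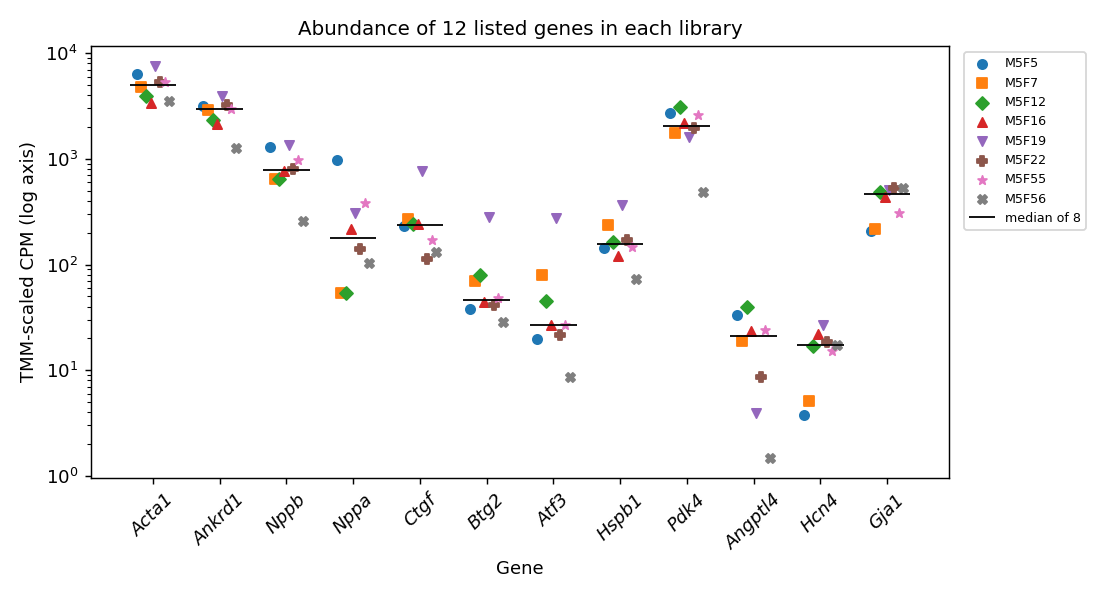
Abundance of 12 genes from the fixed lists in each of the 8 libraries, on a log axis of TMM-scaled CPM, with a marker per library and a line at the median of the 8. Atf3, Btg2 and Ctgf had their highest point in M5F19 (273, 281 and 769 CPM), and M5F56 had the lowest point for Ankrd1, Nppb, Pdk4 and Angptl4.

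The 15 measured immediate early genes had a median fold of 2.28 between the extreme libraries (100th percentile). M5F19 held the highest value of 7 of them, and M5F56 the lowest of only 2, Atf3 and Btg2. Btg2, an antiproliferative early gene, was at 281 CPM in M5F19 and 28.7 in M5F56, and Ier3 was at 40.8 CPM in M5F19 and at most 15.6 elsewhere. Of 12 heat shock genes, 8 were highest in M5F19 and 9 lowest in M5F56, with a median fold of 1.60 (99.6th percentile). Hspb1, a small chaperone, ran from 72.7 to 365 CPM and Hsph1 from 130 to 486 CPM between those 2 libraries. Of 15 genes of the unfolded protein and integrated stress response, 9 were lowest in M5F56, among them Hspa5, the main chaperone of the endoplasmic reticulum, at 539 CPM against 713 to 1010 in the other 7.

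The 3 lists of energy metabolism did not pass the 95th percentile of matched random lists by either range. The median fold was 1.35 for 27 genes of fatty acid oxidation (43.9th percentile, and 85.1st by the trimmed range), 1.31 for 20 nuclear-encoded genes of oxidative phosphorylation (25.6th and 78.3rd) and 1.32 for 18 genes of glycolysis and glucose use (28.3rd and 44.0th). For fatty acid oxidation this turned on single animals, since the trimmed percentile rose past the threshold, to 96.0, 96.2 and 95.7, without M5F5, M5F7 and M5F16. Hadhb, of the mitochondrial trifunctional protein, ran from 2449 to 3822 CPM, Atp5a1, of the ATP synthase, from 3443 to 4068 CPM, and Ldhb, lactate dehydrogenase B, from 4426 to 5119 CPM. Pdk4, the kinase that restrains glucose oxidation, was at 489 CPM in M5F56 against 1604 to 3125 in the other 7, and Ppara, a nuclear receptor of fatty acid use, ran from 24.9 CPM in M5F7 to 84.9 in M5F19. M5F56 held the lowest value of 15 of the 27 fatty acid genes and M5F12 the lowest of 15 of the 20 oxidative phosphorylation genes. M5F12 also held the lowest value of 8 of the 21 sarcomere genes and 5 of the 10 ventricular markers, and the highest of 7 of the 10 macrophage markers; the mix of cells was not measured.

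The 18 measured genes of calcium handling and conduction had a median fold of 1.60 (99.7th percentile), and the widest trimmed ranges among them were those of Hcn4, Gja1, Kcnj2 and the kinase gene Camk2d. Casq2, the calcium store calsequestrin, ran from 2501 to 3027 CPM. Gja1, the main gap junction gene of ventricular muscle, ran from 209 CPM in M5F5 to 535 in M5F22, with a median of 463. Kcnj2, of the inward rectifier current, ran from 33.1 CPM in M5F19 to 99.8 in M5F16. M5F5 held the lowest value of 10 of the 18. The 21 sarcomere genes had a median fold of 1.46 (97.1st percentile), with Ttn, the giant spring titin, from 3301 CPM in M5F22 to 7526 in M5F7. The percentile of the sarcomere list by the trimmed range, 98.8, fell to 88.5 or below on leaving out M5F5, M5F7, M5F12, M5F16 or M5F22 and reached 44.2 without M5F16. It was 90.0 without M5F19 and 89.2 without M5F56.

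Matrix genes also differed among the animals. The 25 measured genes of the matrix list had a median fold of 1.81 (100th percentile), and M5F16 held the lowest value of 13. That library also held the lowest value of 7 of 12 smooth muscle and pericyte markers and 4 of 7 lymphatic markers. The fibroblast markers had their lowest mean log2 CPM in M5F55, 5.76, with 5.77 in M5F16. The mix of cells was not measured. Ctgf, a matricellular growth factor, was at 769 CPM in M5F19 and 113 to 272 in the other 7. Sparc ran from 443 CPM in M5F16 to 928 in M5F7 and Col3a1 from 226 in M5F16 to 391 in M5F19. Postn, which marks activated fibroblasts, ran from 3.35 to 11.6 CPM, and Tnc, expressed in injured matrix, was at 10.8 CPM in M5F12 and at most 5.39 elsewhere.

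**Figure D3:**
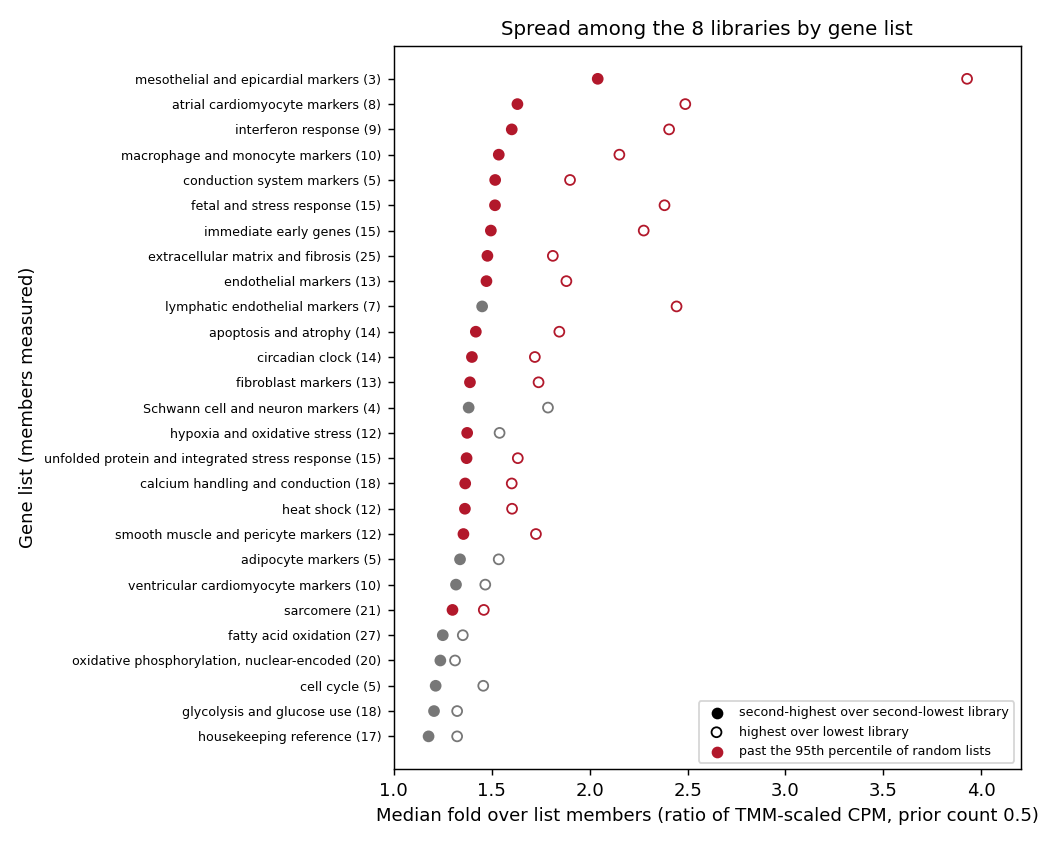
Spread among the 8 libraries for each fixed gene list with at least 3 measured members (number in brackets), as the median over members of the ratio of scaled CPM between the highest and the lowest library (open circles) and between the second-highest and the second-lowest (filled). Red marks a value past the 95th percentile of 10000 abundance-matched random lists, and the housekeeping list has the lowest filled circle.

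Cell type markers also differed between animals. Of 13 endothelial markers (median fold 1.88, 100th percentile), 8 were highest in M5F7, among them Cdh5, the endothelial cadherin, at 417 CPM against 222 to 357 in the others. Of 10 macrophage and monocyte markers (median fold 2.15, 100th percentile), 7 were highest in M5F12 and 5 lowest in M5F5. Csf1r, the receptor that sustains macrophages, ran from 11.9 CPM in M5F5 to 25.1 in M5F12, and C1qc, a complement gene of tissue macrophages, from 12.6 to 28.4 CPM between the same libraries. The trimmed percentile of the macrophage list was 99.8, but 49.9 with a mean count of at least 500 and 93.6 without M5F5. Of 7 lymphatic markers, 6 were highest in M5F7, while Prox1 was lowest there at 27.3 CPM and highest in M5F56 at 82.7. Of 12 smooth muscle and pericyte markers, 7 were lowest in M5F16. Of the 8 measured atrial markers, Nppa among them, 6 spanned 2-fold or more. Tbx5, a cardiac transcription factor, ran from 12.7 CPM in M5F7 to 34.5 in M5F56, and Pam from 1347 to 2066 CPM. Of liver markers, Alb, serum albumin, was at 90.7 CPM in M5F5 and at most 0.822 CPM in the other 7, so its place among the 25 genes with the widest trimmed range rests on few counts.

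Over the 27 lists with at least 3 measured members, 18 lay past the 95th percentile by the full range and 18 by the trimmed range. The sets differed by the lymphatic markers, past it only by the full range (99.9th percentile, and 93.8th by the trimmed range), and by hypoxia and oxidative stress, past it only by the trimmed range (87.4th by the full range). Besides those named above, the trimmed range placed there the lists of the circadian clock (99.3rd percentile), interferon response (99.2nd), hypoxia and oxidative stress (98.0th), apoptosis and atrophy (99.6th), and the markers of atrial cells (99.8th), conduction system (97.9th), fibroblasts (98.9th) and mesothelium (99.1st). The lists not past it were ventricular markers (93.8th), lymphatic markers, adipocyte markers (88.0th), Schwann cell and neuron markers (51.4th), the 17 housekeeping genes (17.9th), the 5 measured cell cycle genes (5.22nd, but 85.0th with no count filter) and the 3 lists of energy metabolism. Some of these placements turned on a single animal. Leaving out M5F7 put hypoxia (91.2), apoptosis (85.4), smooth muscle (88.4) and the unfolded protein response (89.8) under the threshold, and leaving out M5F12 did so for the mesothelium (91.4), interferon (86.6) and the unfolded protein response (86.2). Interferon was at 91.4 and the unfolded protein response at 89.5 without M5F19, interferon at 90.6 without M5F56, conduction at 94.7 and fibroblasts at 91.4 without M5F16, fibroblasts at 92.1 without M5F22 and atrial cells at 92.4 without M5F55. Scaling and filter ended others: fibroblasts were at 94.9 with total counts, smooth muscle at 92.2 with a mean count of at least 500 and the unfolded protein response at 91.5 with no filter. In the other direction, adipocyte markers rose to 96.4 without M5F7 and 96.2 with total counts, and lymphatic markers to 97.1 with total counts, 95.1 with no filter, and 98.7, 96.9, 95.6, 97.0 and 96.0 without M5F5, M5F12, M5F19, M5F22 and M5F55.

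Relations across the 8 animals were examined for 8 pairs of measures fixed in advance, a further 6 that involve Myh6 not being computed. For Nppa with the atrial markers the values fell into separate clusters, so no coefficient is given. None of the other 7 had a Benjamini-Hochberg adjusted p below 0.05, and 1 had an unadjusted p below it. The closest was Nppa with Nppb, with Pearson r = 0.65 (exact permutation p = 0.0754, adjusted p = 0.528) and Spearman rho = 0.81 (exact permutation p = 0.0218, adjusted p = 0.152). Its r was 0.61 after M5F5 and M5F12, the libraries farthest from the Nppa median, were left out. The matrix list with macrophage markers had r = -0.18 (exact permutation p = 0.683; r = -0.57 without M5F12) and rho = -0.12 (p = 0.793), and with the stress list r = 0.32 (exact permutation p = 0.433) and rho = 0.24 (p = 0.582). Their r was -0.056 and 0.32 without M5F16 and M5F22, and all 4 adjusted p-values were 0.815 or more.

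For Nppa with the other stress genes r was 0.35 (exact permutation p = 0.404) and rho 0.36 (p = 0.389), with r = 0.48 without M5F5 and M5F12. Fatty acid oxidation with glycolysis had r = -0.11 (exact permutation p = 0.794) and rho = -0.48 (p = 0.243), with r = -0.14 without M5F12 and M5F56. The clock gene Per2 with the immediate early genes had r = -0.060 (exact permutation p = 0.908) and rho = 0.26 (p = 0.536), with r = -0.55 without M5F7 and M5F56. Oxidative phosphorylation with total counts had r = 0.20 (exact permutation p = 0.640) and rho = 0.024 (p = 0.977), with r = 0.077 without M5F5 and M5F12. The adjusted values of these 4 pairs were 0.815 to 0.977. Genotypes are mixed among the 8 animals in a way the labels do not give, and the labels name no batch or date, so no relation could be recomputed within either.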

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

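Liver lists left out of the counts, and shared members left out of the relations, were settings chosen after the data were seen. The other settings were chosen before. The counts of variable genes followed the count filter. With no filter, 3846 genes spanned 2-fold and 1938 did so by the trimmed range, against 1519 and 311, and with a mean count of at least 500 they were 324 and 86; the cause was not tested. Leaving out 1 library gave 1195 to 1452 genes by the full range and 143 to 276 by the trimmed range, and with 7 libraries a trimmed range is narrower by construction. The lowest trimmed counts were 143 without M5F7 and 169 without M5F5. DESeq2 size factors (1520 and 309), total counts (1571 and 320), a prior count of 5 (1372 and 270), scaling without the 10 most abundant genes (1518 and 308) and leaving out the liver lists (1518 and 310) moved neither count by over 1.5 times. The number of lists past the 95th percentile was 18, and 12 to 20 over the settings. The 12 came with the higher filter, where only 20 lists had 3 measured members. The 20 came with no filter, where lists too small to be placed in the main analysis were placed as well. Of the 6 lists lost at the higher filter, interferon, atrial, conduction and mesothelial markers were not tested there. Of 344 placements of single lists, 306 stayed on their side of the threshold. Of 2080 recomputed ranges of named genes, 1790 moved by less than their counting interval. A full range barely changes unless the library left out was the gene's highest or lowest. Most of the leave-one-out values were therefore nearly fixed in advance. Moves beyond the interval came in 225 of 1664 leave-one-out values and in 65 of 416 under the other scalings.

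No relation passed the adjusted threshold under any setting, and 0 did so in the main analysis. Coefficients changed sign in 10 of 91 recomputations. Oxidative phosphorylation with total counts went to r = -0.094 under total-count scaling. With the median of list members, matrix with macrophage markers went to 0.0899 and Per2 with immediate early genes to 0.0857. With z-scores, fatty acid oxidation with glycolysis went to 0.064 and Per2 with immediate early genes to 0.054. Leaving out 1 library gave r from -0.41 to 0.50 for Per2 with immediate early genes, -0.36 to 0.079 for fatty acid oxidation with glycolysis, -0.094 to 0.35 for oxidative phosphorylation with total counts, -0.039 to 0.50 for matrix with the stress list, -0.57 (without M5F12) to -0.0025 for matrix with macrophage markers, 0.56 to 0.87 for Nppa with Nppb and 0.28 to 0.48 for Nppa with the other stress genes; the cause was not tested. Other settings for Myh6 were not run, since no row carries its symbol. For genes past the filter, no unchanged simulated gene of 10709 met both the 2-fold range and the chi-square threshold. Changed genes were missed, however, since the trimmed range found 74% of those changed 2-fold. Genes under the filter carry a wider counting error.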

Other observations

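The tests of sequencing depth for the liver transcripts and for the immediate early genes were chosen after those results were seen; the other tests below were set before theirs, the one of depth by halving after the thinning value had been seen. Genes singled out here outside the preset rule are Fkbp5, Zbtb16, Errfi1, Arg1, Gc and Fetub, which were chosen after their values were seen. S100a9, a calcium-binding protein of neutrophils, was at 32.2 CPM in M5F12 (95% Poisson interval 29.3 to 35.2) and at 1.07 to 4.51 in the other 7 libraries. Selp, the selectin by which activated endothelium captures leukocytes, was at 36.7 CPM there and 1.36 to 3.92 elsewhere, and Csf3r, the receptor for granulocyte colony-stimulating factor, at 5.55 CPM against at most 1.80. Map7d1 was at 24.0 CPM in M5F22 and 1.14 to 1.78 elsewhere, and Scrn2 at 2.01 CPM in M5F12 and 15.2 to 31.2 elsewhere. Fbxo32, a ubiquitin ligase of muscle atrophy, ran from 53.5 CPM in M5F7 to 241 in M5F22, with Trim63, a second such ligase, from 136 to 266 CPM in the same libraries.

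Of 14 measured clock genes, M5F56 held the lowest value of 4, Per1, Per2, Nr1d1 and Ciart, and the highest of Arntl. Arntl, the activating arm of the clock, had 200 counts there (95% Poisson interval 12.1 to 16.1 CPM) and 2.36 to 6.83 CPM elsewhere, while Per2, Per1 and Nr1d1, of its repressing arm, had their lowest values there (42.1, 91.6 and 88.8 CPM, with medians of 79.4, 149 and 139). The time of day of sampling is not in the labels. Fkbp5, a cochaperone induced by glucocorticoids, was at 6.24 CPM in M5F56 and 23.2 to 53.5 in the others, and Zbtb16 at 7.71 CPM and 30.7 to 66.6, its counts being uncertain for the copy named in the methods. Of the 9 measured interferon genes M5F22 held the highest value of 4. Irf7 ran from 15.3 CPM in M5F56 to 42.2 in M5F12 and Rsad2 from 3.88 CPM in M5F12 to 9.77 in M5F22.

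Several markers of tissues near the heart had few counts or none. Sftpc, of the lung, and Rag1 and Rag2, of the thymus, had no count in any library, though Cd1d of the thymus list was at 40.4 to 56.8 CPM, and Col11a1, of cartilage, was at most 0.273 CPM. Of lymphocyte genes, Lck was at 0.615 to 1.43 CPM, Cd8a at 0.546 to 1.59 and Cd79b at 0.785 to 2.43, while Jchain, of plasma cells, reached 8.61 CPM in M5F55 with a median of 2.51. Alas2, of red cell precursors, was at 11.1 CPM in M5F22 and 23.5 to 33.9 in the others. Atp2a1, of skeletal muscle, was at 1.43 to 2.57 CPM.

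On the leading axis of variation, which held 40.7% of the variance, no single gap between libraries passed 0.5 of the range. That rule looks for 1 wide gap, so it cannot exclude several groups set apart by smaller gaps. Positions were 0.504 for M5F5, 0.560 for M5F7, 0.144 for M5F55, 0.0438 for M5F56, -0.244 for M5F22, -0.278 for M5F12, -0.313 for M5F16 and -0.417 for M5F19, with a largest gap of 0.368 of the range. The atrial marker list did show a gap of 0.541 of its range. Its mean log2 CPM without Nppa was 3.95 in M5F55, 4.07 in M5F7, 4.08 in M5F22, 4.38 in M5F5, 4.50 in M5F56, M5F19 and M5F12, and 4.52 in M5F16.

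Liver transcripts were high in 1 heart library, M5F5. Alb, serum albumin, had 1270 counts in M5F5 (90.7 CPM) and 0.0683 to 0.822 CPM elsewhere, and the 9 liver markers found summed to 1911 counts there against 15 to 42 in the others, all 9 being highest in M5F5. Greater depth of M5F5 is argued against by its total, 0.971 of the median of the others, where Alb was 272-fold higher than in the other 7 pooled. Liver RNA in the tube, at dissection or library preparation, remained a candidate explanation but its preset bound was missed: of 12 further liver genes with at least 20 counts, 8 (a share of 0.667, where 0.8 had been asked) were highest in M5F5, with Gc at 104 counts and Fetub at 95, while Arg1, at 177 counts, was highest in M5F12. No biological explanation was tested, and leaving out the liver lists changed the counts of variable genes to 1518 and 310.

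The immediate early genes, 7 of 15 highest in M5F19, differed by a median of 2.28-fold. The ratio of the highest to the lowest total, 1.12, lay below the lower quartile of the members' folds, 1.84. Those folds are of CPM already scaled for depth, so this comparison cannot decide whether a difference that goes with depth made them. A lower glucocorticoid signal in M5F56, which could go with its low Atf3 and Btg2, was left undecided. Of 11 other glucocorticoid targets, 3 (Per1, Errfi1 and Pdk4), a share of 0.273, were lowest in M5F56, between the preset bounds of 0.25 and 0.5. Per1 is also among the clock genes lowest in that library. A test of M5F56 cannot decide why 7 of the early genes were highest in M5F19. The interval between death and freezing, the hour of sampling and genotype are not in the labels used here and stay open as untested.

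The leading axis set genes such as Klhl31, Kcnj5, Irs2, Hcn4 and Hipk2 against Cnksr3 and Cacna2d3. Alb had the largest weight on the positive side, but this rests on M5F5, with 1270 counts there and 1 to 12 elsewhere. The axis was not recomputed without liver genes. The libraries with the highest totals, M5F19, M5F22 and M5F16, all lay on its negative side, as did M5F12, with the second-lowest total. Thinning every library to 13608500 counts left the axis 40.6% of the variance, but with totals 1.12-fold apart that decides nothing. The counts of M5F19, M5F22, M5F16 and M5F7, the 4 largest libraries, were then halved at random, which put them below all others in depth. The positions correlated with the original ones at 0.999 (0.9 had been asked). Random halving keeps the expected CPM, so this argues only against the counting error that comes with depth. It cannot decide whether a difference between libraries that goes with depth made the axis. A trend with gene abundance is argued against, since removing it in 50 bins, by up to 0.163 log2 units, left 40.8%. RNA integrity, gene length, batch and genotype were not tested and stay open, and the axis is not read here as a genotype.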
